A study of Helicoverpa zea with 12 samples.

How the data were processed

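RNA from the midguts of Helicoverpa zea caterpillars, taken shortly after the moult into the 3rd larval instar, was measured on 12 dual-channel Agilent arrays. Each array held a pool from larvae reared on a cholesterol diet, labelled with Cy3, and a pool from larvae reared on 1 of 3 other sterol diets, labelled with Cy5. The test diets were cholestanol, stigmasterol and cholestan-3-one, with 4 arrays each. Per the labels, a pool held 5 larvae, the 4 arrays of a diet were biological replicates, and 500 ng of total RNA with added spike-in RNA went into each labelling. The sterol doses were not stated in the labels. The dyes were never exchanged between diets. A dye effect specific to a probe therefore added to each comparison with the cholesterol diet, while a dye effect that was equal on all arrays cancelled in the comparisons between the test diets. The 4 arrays of each diet lay on 1 slide with 1 scan, so slide and diet could not be separated, and the planned fit with slide as a block was not run.

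The deposited scanner files, made by the authors with Agilent Feature Extraction 9.1, gave the mean spot intensity and the median local background intensity of both channels, uncorrected. Per the file headers, the processed intensity of each channel had been background-subtracted and dye-normalized within the array by the scanner software. The deposited log ratio was the log10 of the Cy5 over the Cy3 processed signal. The deposited files also held other columns that mark spots as well above background, saturated or outlying, as 0 or 1. The deposited value table held log2 ratios. These were checked against the scanner files and equalled the log2 of the Cy5 over the Cy3 processed signal minus the median of each probe over the 12 arrays, with a slope of 1 on every array. Since that centring removes the mean difference from the cholesterol diet, the table was used only to compare the test diets with each other.

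The arrays carried 43803 gene probes of 60 bases, each spotted once. The files paired 0 of these probes with a gene name or accession, and the reference table held no identifiers that matched them. The keyword lists of gene families chosen in advance could therefore not be tested, and probes are named by the identifiers in the files. In their place, 29 protein motifs were searched in the translated probe sequences with Biopython 1.88 on Python 3.11.15. A motif was used if at least 5 probes carried it and if it was at least 3 times as frequent as in reversed sequences, which left 4 motifs and 42 probes. The motifs were chosen after the files had been opened. Probes sharing at least 30 bases were joined, and the brightest probe of each group that was measured on all arrays was tested.

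The mean intensities were background-corrected with normexp and an offset of 50, then normalized by loess within each array, in limma 3.58.1 on R 4.3.3. Nothing was scaled between arrays. Control spots had weight 0 in the loess fit and were left out of the tests, and spots marked as outliers in either channel were left out on that array. A probe was kept if it was well above background in at least 1 channel on at least 3 of the 4 arrays of at least 1 diet, which kept 29169 probes. Between 140 and 261 of these were not tested in a comparison because every spot of a diet concerned was marked as an outlier. The offset draws ratios of dim probes towards 0.

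One limma model with a coefficient per diet was fitted to the log2 ratios of all 12 arrays, without a replicate block. It had 9 residual and 9.84 prior degrees of freedom. Each diet coefficient was tested against 0, and each pair of test diets was compared by a contrast, both two-sided, with Benjamini-Hochberg adjustment over the probes of a comparison and a threshold of 0.05. Counts of probes that changed at least 2-fold are given beside the counts of all probes past the threshold. The replicate numbers were not taken as pairs. Correlations between arrays with the same number in different diets, after removal of the diet means, lay between 0.00643 and 0.0950 (median 0.0415). Those between different numbers lay between -0.0574 and 0.0282 (median -0.0103). Of 12 arrays, 8 correlated best with their own number in both other diets. A weak link between arrays of the same number thus stays open, and a replicate block is among the alternatives. Motif lists with at least 5 measured probes were tested with limma's camera at a preset correlation of 0.01, adjusted over the 2 lists that qualified within each of the 6 comparisons. An estimated correlation and limma's fry were run beside it. Correlations between diets were computed across probes, which are not independent replicates, and carry no p-value.

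The probes named in the text were chosen by a rule: in each comparison, the 2 probes that rose most and the 2 that fell most among those past the threshold, with the same sign on all 4 arrays or, between test diets, with the 4 values of a diet all on one side of the 4 of the other. The comparisons, tests, this rule and the alternatives were set before the data were examined, except for the motif lists and a scaling on the spike-ins, which were added later. The first run of the motif lists tested and adjusted over all 4 of them, and its p-values were seen before the minimum of 5 measured probes, which had been set for the keyword lists, was applied. The adjustment over all 4 lists is given as an alternative.

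The alternatives were the scanner software's processed signals, no background subtraction, median centring in place of loess, no filter on dim probes, a strict filter that asks for both channels well above background on all 12 arrays, replicate number as a fixed or random block, array weights, only the arrays of the diets compared, the deposited value table, 1 probe per group of overlapping probes, all probes of a group, the Cy5 channel alone, a 2-fold threshold, and each array left out in turn. The model was tested on simulated data with 29169 probes, of which 200 were changed in cholestan-3-one. Of the 50 probes given a 1.2-fold change, it recovered 50 for cholestan-3-one against cholesterol, 48 for cholestan-3-one against cholestanol and 46 for stigmasterol against cholestan-3-one. The simulated noise was independent, with the fitted spread between arrays, and the changes were added to normalized log ratios. It held no dye or slide effect, no further spread between pools and no pull of the offset. The recovery thus does not show that a 1.2-fold effect of a diet would be detected. Figures were drawn with matplotlib 3.10.9. The number of arrays limits the precision of every value.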

Results

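Transcript levels in the midgut of 3rd-instar Helicoverpa zea larvae were compared between a cholesterol diet and 3 diets with another sterol or steroid, on 4 arrays per diet and 12 arrays in all. Each array set a test-diet pool (Cy5) against a cholesterol-diet pool (Cy3), and each pool came from 5 larvae. Cholestanol is cholesterol without the double bond in the ring system. Stigmasterol is a plant sterol that keeps this ring double bond and carries an extra ethyl group and a further double bond in the side chain. Cholestan-3-one is cholestanol with a ketone in place of the hydroxyl group. The median Cy3 signal was 74.6 ± 1.37 on the cholestanol arrays, 73.6 ± 0.806 on the stigmasterol arrays and 72.1 ± 0.514 on the cholestan-3-one arrays (SD, n = 4 each). The median Cy5 signal was 148 ± 3.26, 146 ± 3.47 and 117 ± 2.49 on the same arrays (SD, n = 4 each). Of the gene probes, 65.1%, 65.4% and 61.6% were well above background in Cy5. Log2 ratios correlated across probes at 0.947 to 0.989 between arrays of the same diet and at 0.310 to 0.616 between arrays of different diets. The median residual SD of a probe between arrays of a diet was 0.0651 on the log2 scale. For bright probes it was 0.0573, against 0.0624 between copies of a spike-in spot on the same array. The p-values below rest on this spread between arrays, and whether it includes the spread between pools of larvae could not be told.

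The comparison of cholestanol with cholesterol asks which transcripts respond to the loss of the ring double bond. Of 29029 probes tested, 12332 were higher and 9936 lower on cholestanol at an adjusted p under 0.05 (limma), which is 76.7% of the probes. At least 2-fold changes were found for 792 higher and 103 lower probes, and the 95% interval lay within 2-fold in either direction for 96.3% of probes. That share holds only for this processing: the scanner software's signals gave 2304 higher and 543 lower probes at least 2-fold. The probe that rose most was Har_00045587, with a log2 ratio of 3.46 ± 0.04 (SD, n = 4; SE 0.0335; adjusted p 1.97e-23, limma) and a range over the alternatives from 3.45 to 4.73. It also rose on stigmasterol, by 2.38, but had a log2 ratio of -0.55 on cholestan-3-one. Har_00109321 rose by 3.36 ± 0.04 (SD, n = 4), and its mean log2 ratio was 2.64 on stigmasterol and 3.48 on cholestan-3-one. Har_00034195 fell by 2.45 ± 0.05 and Har_00099368 fell by 2.43 ± 0.04 (SD, n = 4 each). These probes share a stretch of 29 bases, so they do not stand for independent transcripts. As the dyes were not exchanged, a dye effect of a probe is part of this and the next 2 comparisons. The balance of directions rests on the processing: with median centring, 3642 probes were at least 2-fold higher and 26 lower, and with the scanner software's signals 10372 of all called probes were higher and 11741 lower.

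**Figure D1:**
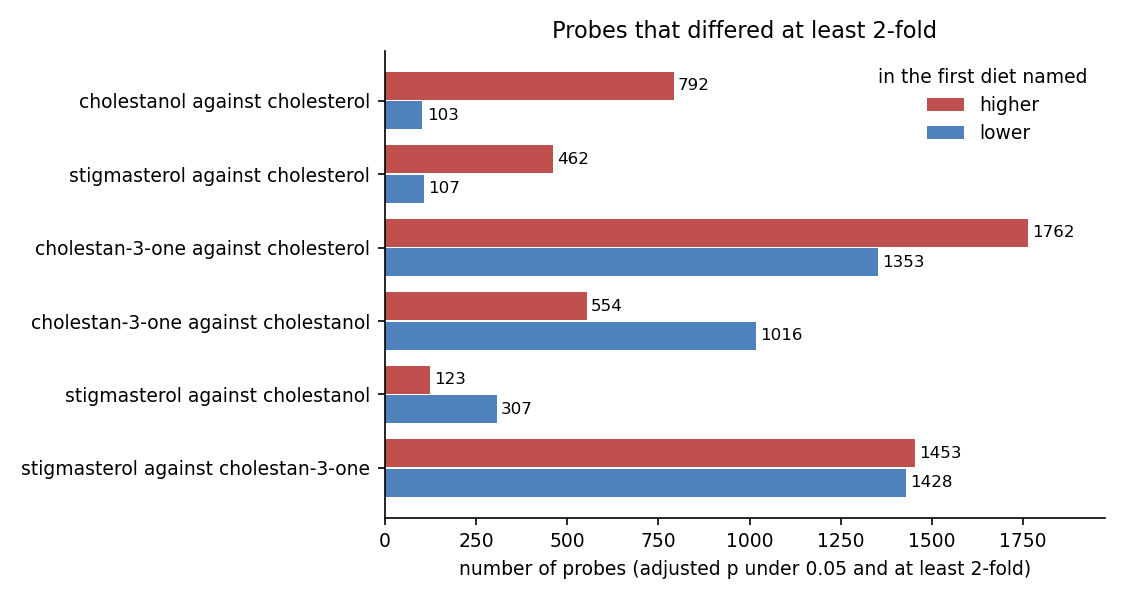
Number of probes that differed at least 2-fold at an adjusted p under 0.05 (horizontal axis) in each of the 6 comparisons; bars show probes higher (red) and lower (blue) in the diet named first. The comparisons that involve cholestan-3-one have 1570 to 3115 probes, above the other 3 under this loess normalization but not with median centring, where cholestan-3-one against cholestanol has 1991 and cholestanol against cholesterol 3668. Among the comparisons with cholesterol, cholestan-3-one keeps the most with median centring.

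The comparison of stigmasterol with cholesterol asks how the midgut responds to a plant sterol with an altered side chain. Of 28998 probes tested, 11749 were higher and 8676 lower, or 70.4% (limma, adjusted p under 0.05). At least 2-fold changes were found for 462 higher and 107 lower probes, and with median centring for 3393 and 46. With the scanner software's signals, 9424 of all called probes were higher and 10553 lower. Har_00113682 rose by 3.04 ± 0.04 on the log2 scale (SD, n = 4; SE 0.0299; adjusted p 5.83e-23, limma), 8.25-fold, with a range over the alternatives from 3.03 to 3.65, and its mean on cholestan-3-one was higher, at 3.34. Har_00134885 rose by 3.02 ± 0.07 (SD, n = 4), against 0.15 on cholestanol and 0.37 on cholestan-3-one. The 2 probes that fell most were the pair with shared bases that also fell on cholestanol and, further, on cholestan-3-one, where the means were -4.18 and -4.19: Har_00099368 fell by 2.63 ± 0.03 and Har_00034195 fell by 2.59 ± 0.03 (SD, n = 4 each).

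The comparison of cholestan-3-one with cholesterol asks about a steroid that has a ketone in place of the hydroxyl group. Of 28922 probes tested, 12416 were higher and 11930 lower, or 84.2% (limma, adjusted p under 0.05). At least 2-fold changes were found for 1762 higher and 1353 lower probes, which is 10.8% of those tested, and the 95% interval lay within 2-fold for 87.3%. With median centring the at least 2-fold counts were 6465 higher and 500 lower, and with the scanner software's signals 4201 and 3087. The 87.3% thus holds only for this processing, whose offset draws ratios of dim probes towards 0. With the strict filter, more of all called probes were lower (10356) than higher (9852). Its total of 24346 called probes exceeded those of the other 2 diets against cholesterol (22268 and 20425), but with median centring it was 25617, below 26210 on cholestanol and 26929 on stigmasterol. The count of at least 2-fold changes on cholestan-3-one stayed above those of the other 2 diets with median centring. More than 8-fold changes numbered 32 higher and 62 lower. Har_00194578, with the sequence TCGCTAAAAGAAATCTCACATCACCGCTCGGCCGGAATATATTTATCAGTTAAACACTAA, fell by 6.37 ± 0.11 on the log2 scale (SD, n = 4; SE 0.0347; adjusted p 1.22e-27, limma), which is 82.5-fold; over the alternatives the log2 value ran from -7.84 to -5.76. Har_00087402, with the sequence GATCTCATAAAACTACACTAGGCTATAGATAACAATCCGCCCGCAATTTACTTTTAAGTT, fell by 5.44 ± 0.11 (SD, n = 4), or 43.4-fold, with a range from -7.16 to -4.89. Har_00030480, with the sequence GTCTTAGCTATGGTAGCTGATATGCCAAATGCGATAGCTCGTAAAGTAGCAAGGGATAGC, rose by 4.32 ± 0.07 on the log2 scale (SD, n = 4), with a range from 4.30 to 5.16. Har_00095065, with the sequence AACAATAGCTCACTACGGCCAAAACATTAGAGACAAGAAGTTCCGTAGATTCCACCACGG, rose by 4.03 ± 0.06 (SD, n = 4), or 16.4-fold, with a range over the alternatives from 4.01 to 4.74. On cholestan-3-one, Har_00194578 and Har_00087402 were well above background on all 4 arrays but dim, with mean log2 signals of 6.40 and 6.39. As the offset draws such ratios towards 0, the sizes of these 2 falls rest on the processing. Changes at least 2-fold against all 3 other diets were found for 407 higher and 687 lower probes on cholestan-3-one, for 44 and 21 on cholestanol, and for 42 and 33 on stigmasterol.

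**Figure D2:**
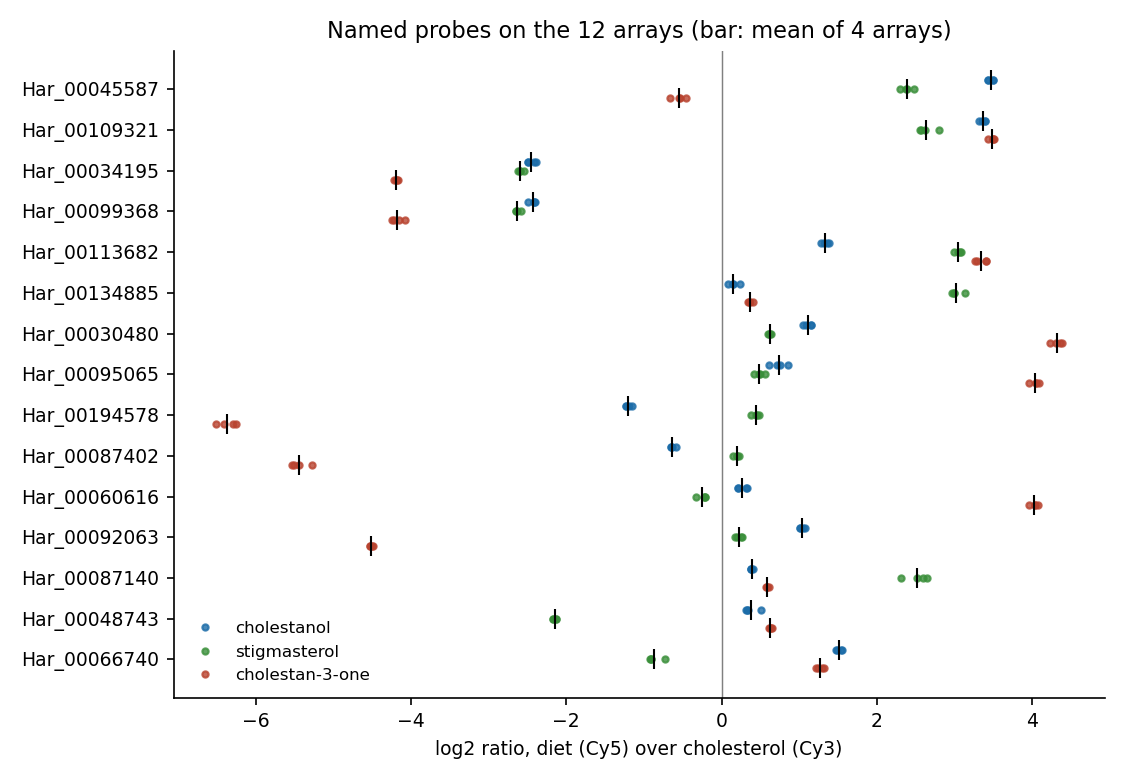
Log2 ratio of each test diet (Cy5) over the cholesterol diet (Cy3) on the horizontal axis for the 15 named probes; each point is 1 of the 4 arrays of a diet and black bars are means. The points of a diet lie close together beside the distances between diets, as for Har_00194578, whose means are -6.37 on cholestan-3-one and 0.44 on stigmasterol.

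The contrast of cholestan-3-one with cholestanol asks about the ketone alone, since both lack the ring double bond. Of 28913 probes tested, 9161 were higher and 10921 lower on cholestan-3-one (limma, adjusted p under 0.05), and 554 were higher and 1016 lower at least 2-fold. Scaling on the spike-ins changed the latter to 269 and 1831, the scanner software's signals to 1841 and 2129, and median centring turned the balance to 1073 higher and 918 lower. Of all called probes, 10546 were higher and 9501 lower with the scanner software's signals, and 14864 and 7803 with median centring. The direction of the balance was thus not settled. Har_00092063 fell by 5.54 on the log2 scale (SE 0.0364; adjusted p 3.92e-26, limma), from 1.03 ± 0.03 on cholestanol to -4.51 ± 0.02 on cholestan-3-one (SD, n = 4 each). Har_00194578 fell by 5.16. Har_00060616 rose by 3.76 and Har_00095065 by 3.30, with all 4 arrays of cholestan-3-one above all 4 of cholestanol.

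The contrast of stigmasterol with cholestanol asks about the ring double bond and the side chain together, and it called the fewest probes. Of 28980 tested, 8944 were higher and 7890 lower on stigmasterol (limma, adjusted p under 0.05), and 123 were higher and 307 lower at least 2-fold. Scaling on the spike-ins gave 190 and 202. Har_00134885 was higher by 2.87 and Har_00087140 by 2.13 on the log2 scale (SE 0.0436 and 0.0544; limma adjusted p 2.81e-19 and 8.84e-17). Har_00048743 fell by 2.52 and Har_00066740 fell by 2.38, with the 4 arrays of each diet apart.

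The contrast of stigmasterol with cholestan-3-one spans the ring double bond, the side chain and the ketone. Of 28908 probes tested, 12198 were higher and 9827 lower on stigmasterol (limma, adjusted p under 0.05), and 1453 were higher and 1428 lower at least 2-fold. Scaling on the spike-ins gave 3705 and 525 at least 2-fold, while median centring gave 1546 and 2123, with 9938 higher and 14243 lower at any size. At least 2-fold lower probes also outnumbered higher ones with the scanner software's signals (2970 and 3325), the strict filter (1311 and 1357) and the Cy5 channel alone (1437 and 1583). The deposited value table gave 2980 and 3330, but it holds the same processed signals centred per probe and is no separate support. Har_00194578 was higher by 6.81 on the log2 scale (112-fold; SE 0.0491; adjusted p 2.36e-25, limma) and Har_00087402 by 5.63. Over the alternatives these values ran from 6.76 to 8.27 and from 5.60 to 7.33. Both probes were dim on cholestan-3-one (mean log2 signal 6.40 and 6.39), so the sizes rest on the processing. Har_00030480 fell by 3.71. Har_00060616 was well above background on 0 of the 4 stigmasterol arrays, so no fold is given; its fitted log2 ratio fell by 4.27 against cholestan-3-one, and over the alternatives this value ran from -6.69 to -3.87. Slide and diet cannot be told apart in any of the 6 comparisons.

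The overlap of the 3 diets shows how much of each difference from cholesterol was common. At least 2-fold changes in the same direction on all 3 diets were found for 153 higher and 22 lower probes. The scanner software's signals gave 957 and 93, and median centring 1560 and 8. At any size, 5962 probes were higher and 4240 lower on all 3, which became 4907 and 5331 with the scanner software's signals and 15603 and 2215 with median centring. Under the loess normalization, independent lists of the same sizes would share 2114 higher and 1209 lower probes at any size. At least 2-fold they would share 0.758 and 0.0175. Part of the count at any size thus follows from the sizes of the lists. In 5 simulations of unchanged groups with shared controls, at most 0 probes were called in the same direction on all 3 diets. Unchanged groups give few calls at an adjusted p under 0.05 by construction, so this 0 is no measure for the counts above. Simulations with shared controls, here and for the correlations below, hold no dye effect. They also hold no deviation of a control pool that is the same on all arrays. Cholestanol and stigmasterol shared 282 probes that rose at least 2-fold, and 1 probe changed at least 2-fold in opposite directions. These numbers were 448 and 30 for cholestanol and cholestan-3-one, and 191 and 23 for stigmasterol and cholestan-3-one. At any size, 3065, 3291 and 5780 probes were called in opposite directions in these pairs, in the same order. The log2 ratios had the same sign for 71.4%, 75.3% and 62.3% of probes. Across 28906 probes, the log2 ratios correlated at r = 0.62 between cholestanol and stigmasterol, 0.60 between cholestanol and cholestan-3-one, and 0.32 between stigmasterol and cholestan-3-one. Unchanged groups simulated against shared controls gave r near 0.50, but covariances of 0.000603, 0.000602 and 0.000602, against measured covariances of 0.0775, 0.154 and 0.0682. When the diets of a pair were represented by arrays with different replicate numbers, r was 0.616, 0.595 and 0.313.

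**Figure D3:**
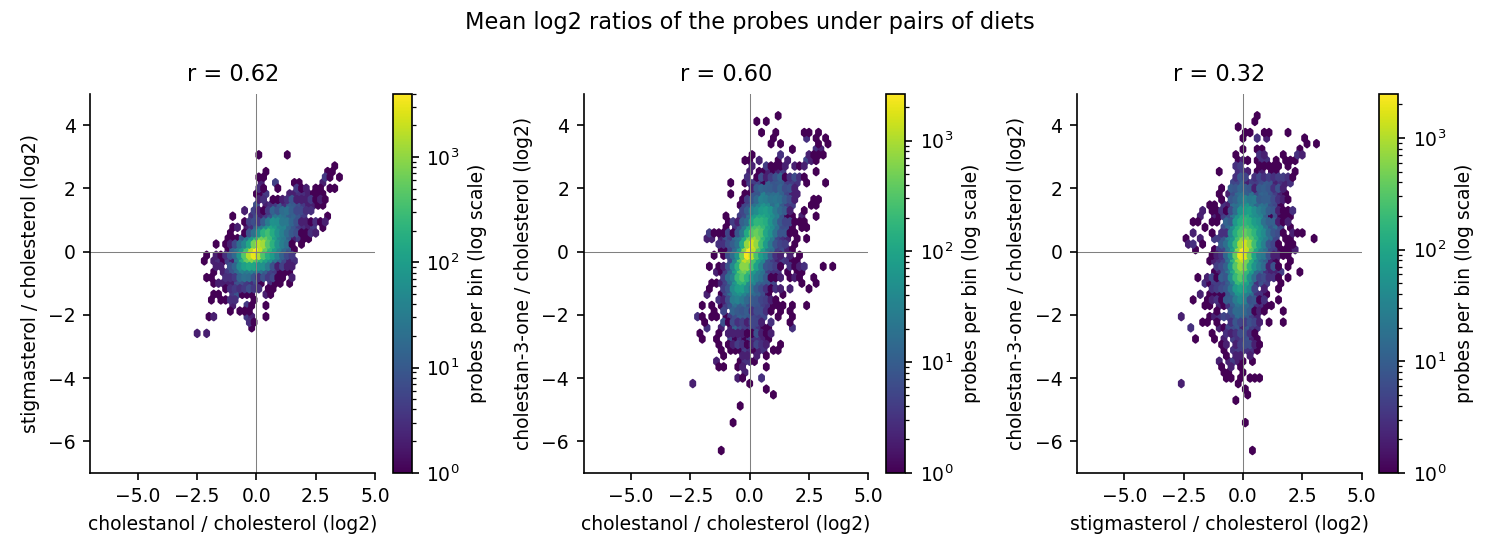
Mean log2 ratios over the cholesterol diet of the probes on pairs of test diets (both axes log2), with the number of probes per bin as colour on a log scale. The pair cholestanol and stigmasterol has r = 0.62 and the pair stigmasterol and cholestan-3-one r = 0.32.

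Probes whose translation carries the haem-binding motif of cytochrome P450 enzymes, which oxidise steroids and plant compounds, were tested as a list, as were those with the catalytic-histidine motif of trypsin-like serine proteases. Of 13 probes with the P450 motif, 9 could be tested. On cholestan-3-one against cholesterol, 8 were higher and 1 lower, with a median log2 change of 0.46 (camera p 0.00415, adjusted 0.00831, limma). All 9 were past the threshold over all probes, and 9 when adjusted over the list alone. As 84.2% of all tested probes were called in this comparison, that count does not set the list apart. On cholestan-3-one against cholestanol, 7 were higher and 1 lower, with a median of 0.58 (camera p 0.000402, adjusted 0.000805, limma). On stigmasterol against cholestanol, 7 were higher and 1 lower, with a median of 0.40 (camera p 0.00178, adjusted 0.00355, limma). The medians of these 3 comparisons stayed positive under every scaling that was run for them, but their sizes moved. They ran from 0.46 to 1.5 (median centring) for the first, from 0.31 (spike-in scaling) to 1.01 (scanner software's signals) for the second, and from 0.40 to 0.53 (spike-in scaling) for the third. With an estimated correlation the adjusted values were 0.0309, 0.0102 and 0.0200, and adjusting over all 4 motif lists as well gave 0.0619, 0.0204 and 0.0401. The call for cholestan-3-one against cholesterol ended only with both choices together, since adjusting over 4 lists at the preset correlation gave 0.0166. No shift of the list was detected on cholestanol or stigmasterol against cholesterol, or between stigmasterol and cholestan-3-one (limma camera adjusted p 0.869, 0.299 and 0.193). Spike-in scaling brought the last of these past the threshold (limma camera adjusted p 0.0211). The list median was then only -0.0921, with 4 of 9 probes above 0, while the median of all probes was 0.442. That call is thus relative to the other probes. The median of the list on cholestanol was -0.10, but 0.63 with median centring, where the median of all probes was 0.37. The 10 serine protease probes tested gave adjusted p from 0.307 to 0.983 (limma camera). For cholestan-3-one against cholesterol their median of 0.12 and their mean of -0.12 differed in sign. A second serine protease motif had 4 measured probes and a carboxylesterase motif 3, under the minimum of 5. They had been tested in the first run over all 4 lists, and neither passed the threshold in any comparison (limma camera, adjusted p 0.483 to 0.953 for the serine protease motif and 0.0796 to 0.579 for the carboxylesterase motif). Of the 3 carboxylesterase probes, 2 were higher and 0 lower on cholestanol against cholesterol, 0 and 1 on stigmasterol, and 3 and 0 on cholestan-3-one. Between test diets, 3 were higher and 0 lower on cholestan-3-one against cholestanol, 0 and 2 on stigmasterol against cholestanol, and 0 and 3 on stigmasterol against cholestan-3-one. Of all tested probes, 58.1% to 84.2% were called in a comparison, so the number called does not set these probes apart.

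**Figure D4:**
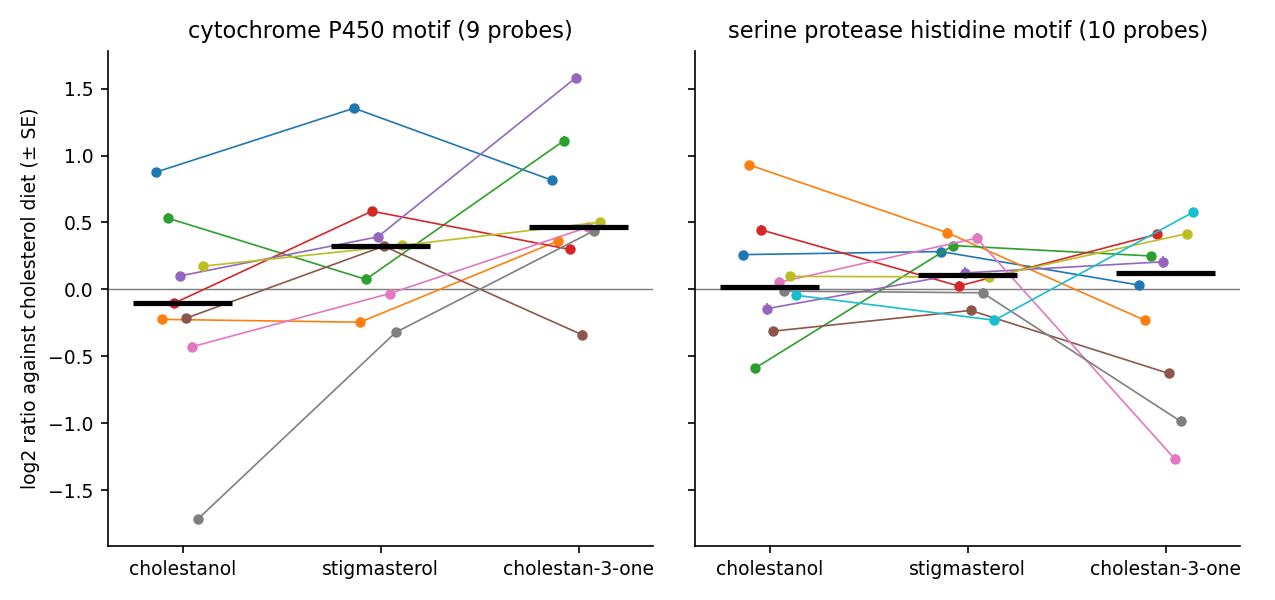
Log2 ratio against the cholesterol diet on the 3 test diets for probes with the cytochrome P450 motif (9 probes, left) and the serine protease histidine motif (10 probes, right); each line is a probe, error bars are SE and mostly smaller than the points, and black bars are medians. The P450 median is 0.46 on cholestan-3-one and -0.10 on cholestanol. With median centring these medians are 1.5 and 0.63, so the sign on cholestanol turns, but the median of all probes is then 0.36 and 0.37. With the scanner software's signals the cholestan-3-one median is 0.95.

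Spike-in RNA, added to each labelling, gave a reference outside the larvae. The mean log2 ratio of 10 spike-ins after loess was -0.03 on the cholestanol arrays (SD 0.0015), -0.16 on the stigmasterol arrays (SD 0.0045) and 0.24 on the cholestan-3-one arrays (SD 0.0051, n = 4 each). The spread between arrays of a diet was far smaller than these differences between slides.

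**Figure D5:**
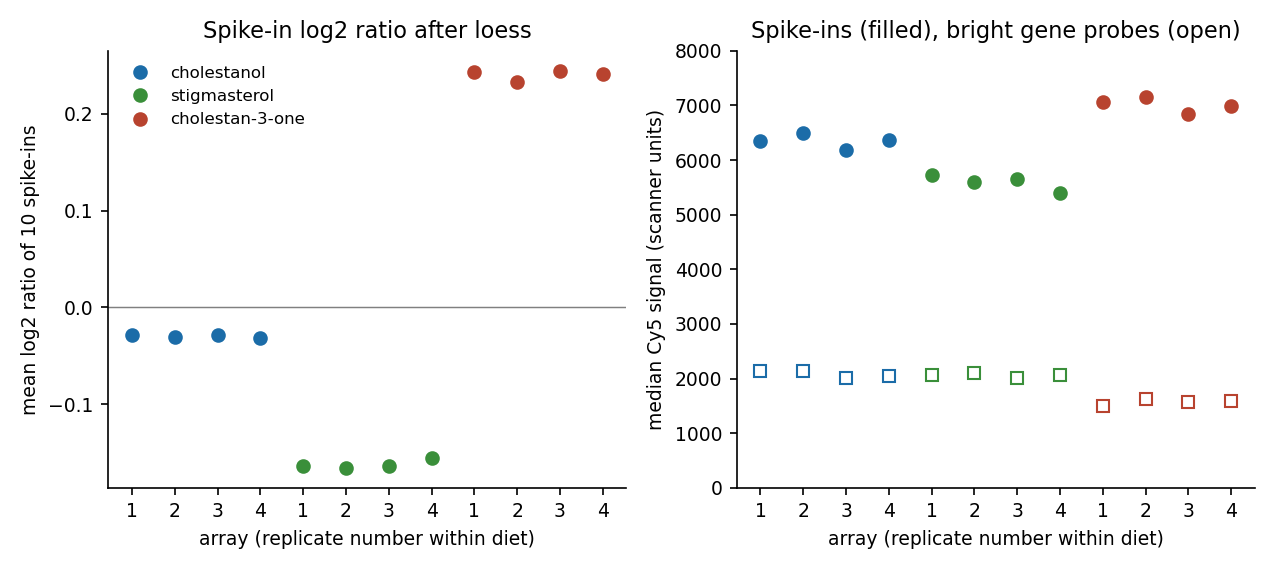
Mean log2 ratio of 10 spike-ins after loess (left) and median Cy5 signal in scanner units (right) of spike-ins (filled) and bright gene probes (open) on the 12 arrays, 4 per diet. On the cholestan-3-one arrays the spike-in ratio averages 0.24, with a spike-in Cy5 signal of 7007 and a gene probe signal of 1576, against 6348 and 2084 on the cholestanol arrays.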

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

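The tests of the spike-ins in this part were chosen after the spike-in values had been seen; the counts over other splits of the arrays were planned.

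The test diets differed from each other by a direct test of the difference. At least 2-fold differences numbered 1570 probes for cholestan-3-one against cholestanol, 430 for stigmasterol against cholestanol and 2881 for stigmasterol against cholestan-3-one. Each pair of diets has 35 splits of its 8 arrays into groups of 4. In each pair, 1 of the 35 splits, the real one, gave as many probes past the threshold. The real counts were 20082, 16834 and 22025, and the highest of the other splits gave 6, 2 and 6. No other grouping of the arrays thus came near the real counts. Slide is not excluded, since each diet lay on its own slide. Chance differences between pools of larvae are not excluded either, since the arrays of a diet may hold the same RNA.

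The list of probes with the cytochrome P450 motif differed between cholestan-3-one and cholestanol (limma camera, adjusted p 0.000805, 7 probes higher and 1 lower) and between stigmasterol and cholestanol (adjusted p 0.00355, 7 higher and 1 lower). In both contrasts 1 of the 35 splits, the real one, gave an adjusted p as low, and the lowest of the others were 0.00729 and 0.0173. Both of these also lie under 0.05, so a grouping that mixes the diets can pass the threshold. The splits are therefore no support for the list. Over the alternatives apart from fry, the adjusted p lay between 5.78e-06 and 0.0204 for the first contrast and between 0.000493 and 0.0401 for the second. The motif was carried by 1 probe in reversed sequences against 13 in the real ones.

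The spike-ins stood apart on the cholestan-3-one slide. Their mean log2 ratio was higher by 0.27 than on the cholestanol slide (SD over 10 spike-ins 0.124), and stigmasterol minus cholestan-3-one was -0.40. A lower Cy5 dye yield or scanner gain on that slide would lower spike-ins and gene probes together, but the spike-in Cy5 signal was higher than on the cholestanol slide by 0.14 on the log2 scale while that of bright gene probes was 0.756 of it. The loess step as the whole cause is argued against by the values before normalization. There the median of spike-ins minus that of bright gene probes already differed by 0.47 between these slides, with an SD over 4 arrays of at most 0.0129. Less labelled messenger RNA per unit of spike-in in the cholestan-3-one samples stays open: 10 of 10 spike-ins were higher than on both other slides. An unequal dose of spike-in gives the same picture and cannot be told apart from it with 1 slide per diet, so a biological explanation was not separated from a technical one.

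A single array stood far from the other 3 of its diet for 4 values. These were the log2 ratio of Har_00066740 on stigmasterol replicate 4, at -0.73 against -0.92 to -0.91, and of Har_00134885 on stigmasterol replicate 4, at 3.13 against 2.97 to 2.99. The others were Har_00099368 on cholestanol replicate 4, at -2.49 against -2.42 to -2.41, and Har_00087140 on cholestanol replicate 4, at 0.41 against 0.37 to 0.38. Of 81 groups of 4 arrays tested, 4 had such an array, where chance gives 4.05.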

How the results depend on the processing

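Scaling on the spike-ins and the motif lists were chosen after seeing the data. All 4 lists were tested first, and the restriction to the 2 lists with at least 5 measured probes was applied after those p-values were seen. All 417 values of the named probes kept their sign and stayed past the threshold under the alternatives that gave them a value. The strict filter gave none for Har_00045587 and Har_00060616, which it removes. Their sizes moved: with the scanner software's signals Har_00194578 went from 6.81 to 8.27 for stigmasterol against cholestan-3-one; the cause was not tested. With each array left out in turn, no count moved by more than 1.5 times and no motif list changed its call. Values below follow the order cholestanol, stigmasterol and cholestan-3-one against cholesterol, and for the contrasts cholestan-3-one against cholestanol, stigmasterol against cholestanol and stigmasterol against cholestan-3-one.

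Counts of at least 2-fold changes follow the processing. With the scanner software's signals they were 2847, 2290 and 7288 against cholesterol, 3970, 1397 and 6295 in the contrasts, and 1050 in the same direction on all 3 diets. The deposited value table gave 3975, 1414 and 6310 for the contrasts. It holds the same processed signals centred per probe, so it is no separate alternative there. Why the counts rise with these signals was not tested. With median centring the counts against cholesterol were 3668, 3439 and 6965, and the probes changed in the same direction on all 3 diets numbered 17818, with 1568 at least 2-fold. This centring moved the median of all probes to 0.37, 0.47 and 0.36 on the log2 scale against cholesterol, which raises the number called higher. Asking for 2-fold changes as a threshold brings the counts to 895, 569, 3115, 1570, 430 and 2881 by construction.

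Spike-in scaling kept the counts of the contrasts within 1.5 times but moved the median of all probes to -0.29, 0.15 and 0.44, so the share of higher probes depends on it. Past the threshold, 3648 probes were then higher and 21370 lower in the first contrast, 16728 and 4627 in the second, and 22801 and 3915 in the third. It also brought the P450 list past the threshold in the third (limma camera, adjusted p 0.0211, other alternatives 0.0877 to 0.519 apart from fry). The median of the list itself moved from -0.495 to -0.0921, so this call does not mean a larger change of its probes. The cause was not tested.

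Correlations of cholestanol with stigmasterol, cholestanol with cholestan-3-one and stigmasterol with cholestan-3-one stayed positive. They were 0.633, 0.602 and 0.329 without background subtraction, 0.783, 0.673 and 0.474 with median centring, and 0.606, 0.634 and 0.317 with the strict filter. The scanner software's signals gave 0.713 for the first pair and 0.435 for the last, and no filter gave 0.601 for the second; the cause was not tested.

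The P450 call for cholestan-3-one against cholesterol ended at an adjusted p of 0.0619 with the estimated correlation and adjustment over all 4 lists together. Each alone kept it, at 0.0309 and 0.0166. Fry asks whether a list moves on balance one way and does not compare it with other probes, so it called lists that camera did not. For the P450 list it gave 9.53e-07 and 6.86e-10 on cholestanol and stigmasterol against cholesterol and 2.03e-08 in the third contrast. For the serine protease list it gave 0.000362 and 2.68e-06 on cholestanol and stigmasterol, and 4.76e-06, 0.00820 and 3.24e-07 in the contrasts. On cholestan-3-one against cholesterol it gave the serine protease list 2.35e-05 in the direction of its mean, opposite to camera; the mean and median of the list differ in sign.

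A replicate block gave 22396, 20554 and 24434 probes against cholesterol and 20260, 17086 and 22207 in the contrasts. Of the at least 2-fold changes, 4 to 142 per comparison had a dim side not well above background on all arrays, which limits their folds.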

Other observations

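The tests of the spread between arrays, of shared control noise and of an equal dye bias were chosen after the results were seen; the test of base composition and the counts over sign arrangements were planned.

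Arrays of the same diet differed as little as copies of a spot. The median residual SD of 15683 bright probes between arrays of a diet was 0.0573, against 0.0624 between copies of a spike-in spot on an array. After adjustment, 130 of these bright probes had a residual SD above that between copies of a spot. The 99th percentile of the residual SD of bright probes was 0.111, and the median between-array component SD was 0. A spread between arrays beyond the noise of a spot was thus detected for few bright probes. Technical replicates of the same RNA could give these values. A small spread between pools of 5 larvae could also lie under the noise of a spot, so these cannot be told apart here. The labels call the arrays biological replicates.

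The 3 test diets shared part of their difference from cholesterol. Noise of shared controls of the size seen between arrays of a diet is argued against as the cause. The lowest covariance of the 3 pairs of diets was 113 times the highest simulated for such noise. A deviation of a control pool that was the same on all arrays would not be part of that spread. The simulation does not hold it, so it stays open. A dye bias that is equal on all arrays is argued against as the whole cause, since it would give equal covariances, while they differed by 0.0858 between pairs, with a range of 0.000971 over arrays left out. A dye bias that follows the base composition of the probes is argued against by the 0.744% of the variance of the mean log2 ratio that base composition explained. A response to the lack of cholesterol that is common to the 3 diets stays open, as does a dye bias as part of the cause: with 0 dye-swapped arrays they cannot be told apart.

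Each comparison with cholesterol has 8 arrangements of the signs of its 4 arrays, too few for a share under 0.05. The real arrangement was the 1 with the most probes past the threshold in each: 22268 for cholestanol, 20425 for stigmasterol and 24346 for cholestan-3-one, where the highest of the others gave 84, 116 and 440. For the P450 list on cholestan-3-one against cholesterol, the adjusted p (limma camera) was 0.00831 and the lowest of the others 0.0157, also under 0.05. For the probes changed in the same direction on all 3 diets, 1 of 100 sign arrangements of the 12 arrays, the real one, gave as many as 10202. The highest of the others gave 23, so random signs did not give that count. A dye effect of a probe, or arrays of a diet that hold the same RNA, would give this outcome too, so neither is excluded.

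Probes that overlap on the same strand gave like values. The log2 ratios of 1997 bright pairs correlated at 0.970, 0.972 and 0.981 on cholestanol, stigmasterol and cholestan-3-one. Bright pairs on opposite strands, of which there were 284, correlated at 0.448, 0.468 and 0.252, where shuffled pairs gave 0.110, -0.0147 and 0.0259.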
